A study of Arabidopsis thaliana with 6 samples.

How the data were processed

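Transcript counts of 6 libraries were analysed, 2 from each of 3 transgenic Arabidopsis thaliana lines of the Columbia ecotype. Per the labels, the lines carried YFP-tagged BRX under the BRX promoter, YFP-tagged BRXL2 under the BRXL2 promoter, or a YFP-tagged construct named myrBRX. The series describes the samples as stomatal lineage ground cells, the larger cells left by asymmetric divisions in the leaf epidermis. True leaves were taken 9 days post germination from plants kept 2 days in the cold and then grown at 22 °C under 16 h of light and 8 h of dark. RNA came from about 20000 sorted cells per sample, and the gate was not given in the sources used here. From each sample, 20 ng of total RNA with an integrity number above 8 was amplified with the Ovation RNA-Seq System V2 and sequenced on an Illumina instrument.

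The deposited values are raw counts per TAIR10 locus, 1 library per table, with no normalisation. The unit was read from the values, which are whole numbers with a different total in each library. Reads were aligned to TAIR10 with Bowtie2, per the submitters' processing notes. The counting program, its strand setting, its handling of reads that align to several places and the annotation release were not given in the sources used here. Counts of close paralogs such as TGG1 and TGG2 may therefore share reads, and antisense reads could be included in any gene. A construct and its endogenous gene were counted together. Locus identifiers were matched to a TAIR10.1 annotation for names and for transcript length and GC content; no coordinates were used, since the builds differ. Of 33602 loci, 32835 were matched and 10654 had a symbol.

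The libraries held 25817906 to 42113178 counts. A count of 0 was read with a floor of 3 counts per library, which corresponded to 0.0638 to 0.0992 CPM (counts scaled to a common library size with the TMM factors). Amplified reads without molecular identifiers are not independent molecules, so intervals (95%, exact Poisson on the counts of the group with few) and floors cover counting error only. The labels do not say whether the 2 libraries of a line came from separate cultures, so each p measures only the spread between these samples, which may be technical. The tables of a line were not copies of each other: the chi-square per gene between them was 649.3 to 979.9, which separate amplifications of 1 RNA could also give.

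Differences were tested with edgeR 4.0.16 under R 4.3.3, with limma 3.58.1 for gene lists. Loci were filtered with filterByExpr at its minimum of 10 counts, which left 18174, and scaled with TMM factors. A quasi-likelihood fit (glmQLFit and glmQLFTest at their defaults, two-sided) held 1 coefficient per genotype and all 6 libraries, with 3 residual degrees of freedom. The common dispersion was 0.781, a biological coefficient of variation of 0.884. Each pair of genotypes was compared, and a further test asked for any difference among the 3. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Log2 fold changes are given ± SE from this fit, and CPM as mean ± SD of n = 2 libraries. Where every library of a group was at 0, the fold is a bound against the floor; where a group held 1 to 3 counts, the ratio is given with its counting interval.

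Gene lists were fixed before the data were examined: stomatal lineage regulators, the BRX family, guard cell markers, epidermal markers, mesophyll and photosynthesis genes, phloem and vascular markers, trichome genes, G2/M cell cycle genes, S phase and replication genes, D-type cyclins with cyclin-dependent kinase inhibitors, brassinosteroid genes, auxin response genes, auxin transport genes, cytokinin response regulators, jasmonate and wound genes, rapid stress genes, heat shock genes, salicylate and defence genes, abscisic acid and cold genes, circadian clock genes, and cell wall expansion genes. Of 251 entries, 249 matched their locus in the reference; PAX and PME6 did not and were left out. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 60 tests of 20 lists in 3 comparisons. The trichome list had 2 testable genes of 8 and was not tested. All camera calls were repeated with a correlation estimated per list and with fry.

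Genes named in the text follow a rule fixed before the data were examined. For each comparison these were the 8 higher and 8 lower genes with the largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 3, a symbol and no overlap between the groups. BRX and BRXL2, called list members, and SPCH, MUTE, FAMA, TMM, BASL and POLAR were always named. Where fewer than 16 genes met all these conditions, as in each comparison, the 5 genes with the lowest p were named in each direction. All other genes were chosen after their values were seen, including the loci without a symbol and the remaining examples from gene lists, most of which are among the 4 members of lowest p in a called list.

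The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 2 CPM in 2 libraries, a fit of the compared groups alone, robust fitting, organelle loci left out, the replicate number as a block, and each library left out in turn. A newer edgeR fit, the omission of the locus AT1G79245, and further scalings for the gene lists were added after the data were seen. The tests were tested on simulated data with the dispersions of these libraries. With 50 genes at each change, edgeR recovered between 0 and 1 at 4-fold, 8 to 21 at 16-fold, 26 to 35 at 64-fold and 34 to 41 at 256-fold, and 3.53 to 9.88% of its calls were false. DESeq2 gave 52 to 54% false calls there. EdgeR without a filter gave 3.33 to 13.5%, on the same 18174 genes, so loci that the filter removes were not covered. These shares depend on how many genes the simulation changed, and its dispersions were those estimated by edgeR. They do not give the share of false calls in the real data. In the simulation camera called a shifted list, and 4 of 100 unshifted lists fell under 0.05. Each gene was drawn on its own there and the unshifted lists held random genes. Lists whose genes vary together were therefore not covered, and the result does not show that camera holds its level for them. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.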

Results

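RNA sequencing counts were available for sorted stomatal lineage ground cells of 3 Arabidopsis lines, 2 libraries per line. The lines are named here by the construct they carried: BRX, BRXL2 and myrBRX, each tagged with YFP. BRX (BREVIS RADIX) and its relative BRXL2 are plant proteins that take part in cell polarity and in phloem development. The libraries held 25817906 and 35490278 counts for BRX, 35981786 and 42113178 for BRXL2, and 39085068 and 41096714 for myrBRX. No untransformed control was analysed here, so the lines were compared with each other.

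The composition of the libraries differed between lines and between libraries of a line. Chloroplast and mitochondrial loci held 4.55 ± 1.11% of the counts in the libraries labelled BRX, 2.02 ± 0.426% in BRXL2 and 0.949 ± 0.552% in myrBRX (SD, n = 2). A single transcribed pseudogene, AT1G79245, held 14.8 ± 7.02%, 6.89 ± 2.92% and 6.51 ± 0.543% of the counts. Across genes, which are not independent replicates, log2 CPM correlated at 0.737 between the BRX libraries, 0.765 between the BRXL2 libraries and 0.88 between the myrBRX libraries. Libraries of different lines correlated at 0.634 to 0.8. The highest of these values was between BRX 2 and myrBRX 1. BRX 2 correlated with each library of the other lines, at 0.753 to 0.8, above its 0.737 with BRX 1. BRX 1 correlated with those libraries at 0.634 to 0.735.

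The genes of the constructs were examined first. BRXL2 was most abundant in the BRXL2 line, at 1470 ± 136 CPM, against 123 ± 38.6 in the libraries labelled BRX and 17 ± 6.34 in myrBRX (SD, n = 2). It differed among the 3 lines (adjusted p = 0.045, edgeR quasi-likelihood test). BRX had its lowest level in the libraries labelled BRX, at 8.92 ± 3.98 CPM, against 27.3 ± 6.45 in BRXL2 and 52.5 ± 28.5 in myrBRX. BRXL2, the line without a BRX construct, thus stood above a line labelled with one. Whether the same kind of cells was sorted from each line is not known from the labels, and the difference did not pass. The group is called the libraries labelled BRX, and every direction that involves it or myrBRX carries the doubt that these 2 labels were not verified by the BRX level. The pairwise tests of BRX did not pass: the log2 fold change was 2.56 ± 0.85 for myrBRX against BRX (adjusted p = 0.256), 1.61 ± 0.82 for BRXL2 against BRX (0.596) and 0.94 ± 0.81 for myrBRX against BRXL2 (0.67), the last being 0.24 without myrBRX 2 and 1.42 without myrBRX 1. For BRXL2 these values were -2.85 ± 0.92 (adjusted p = 0.249), 3.59 ± 0.95 (0.365) and -6.43 ± 1.09 (0.0747). The last passed with some libraries left out and not with others: adjusted p = 0.0163 without BRX 1, 0.0252 without BRX 2, 0.0428 without BRXL2 1, 0.0141 without BRXL2 2, 0.134 without myrBRX 1 and 0.298 without myrBRX 2.

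**Figure D1:**
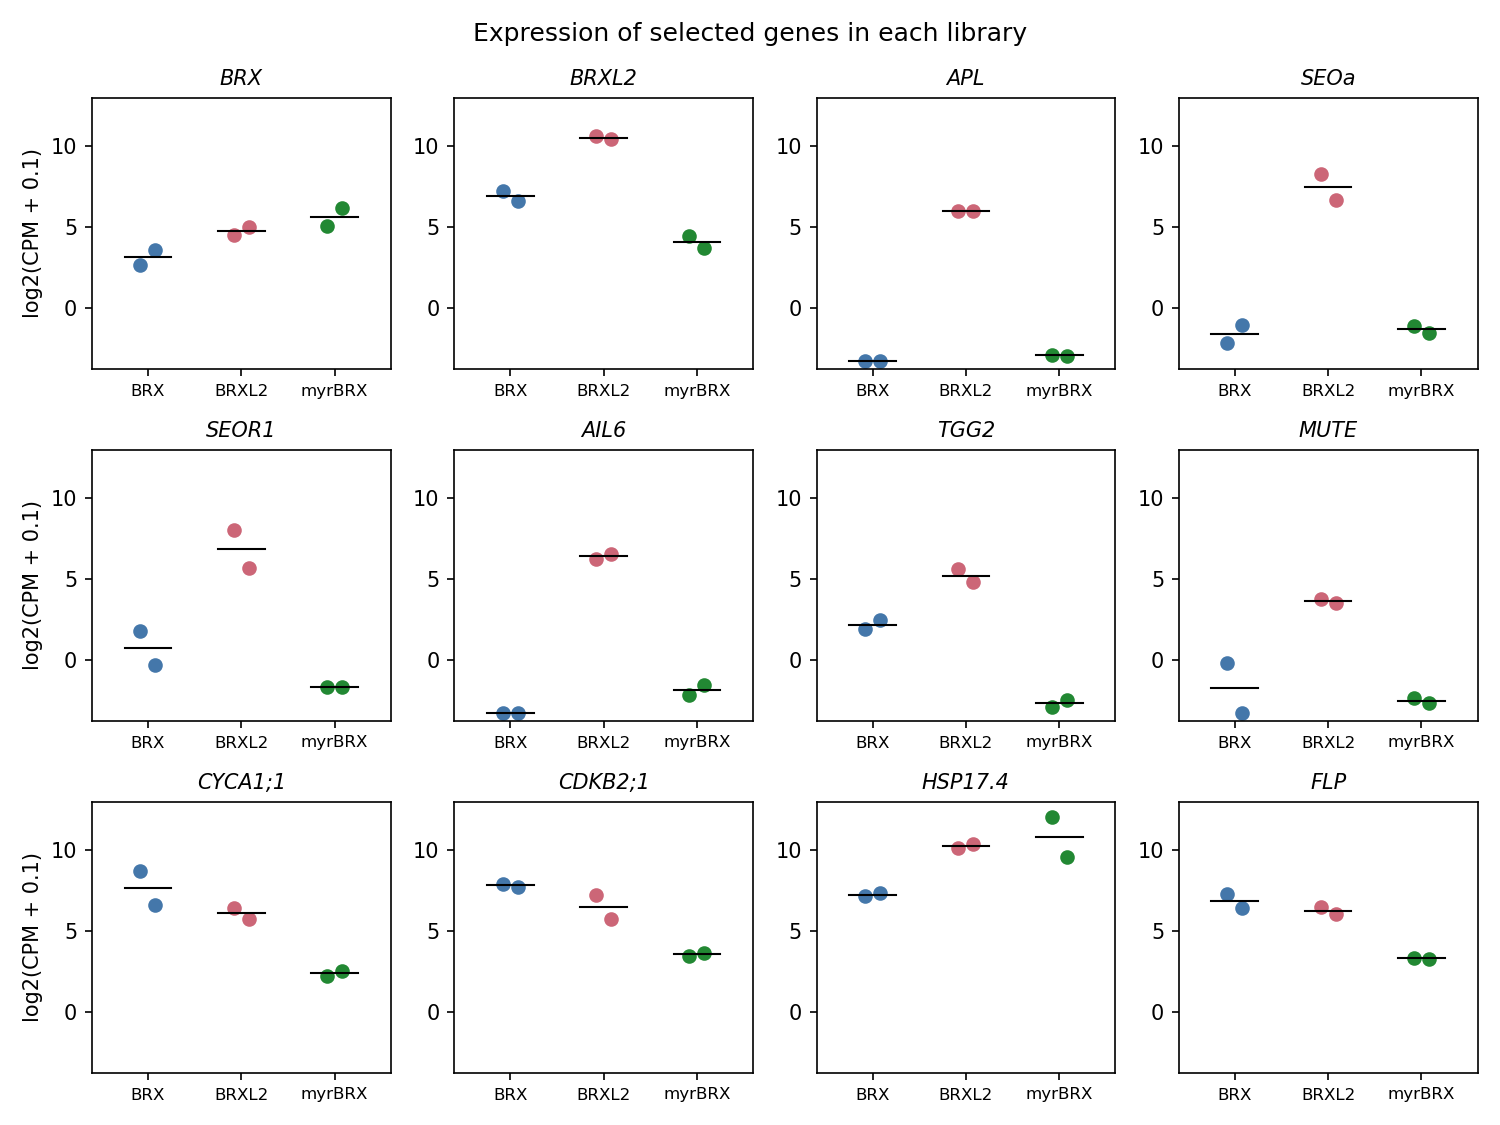
Level of 12 genes in each library, as log2(CPM + 0.1) on the vertical axis, by line on the horizontal axis; each point is 1 library and each bar the mean of 2. APL, SEOa and AIL6 stood high in both BRXL2 libraries (APL at 63.1 ± 1.21 CPM) and near 0 in the others, while BRX was lowest in the libraries labelled BRX; CYCA1;1, CDKB2;1, HSP17.4 and FLP were chosen after their values were seen.

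The comparison of BRXL2 with the libraries labelled BRX asked how cells marked by these related proteins differ in their transcripts. Regulators and structural genes of the phloem, the tissue that carries sugars, were higher in BRXL2. APL, a transcription factor needed for phloem identity, stood at 63.1 ± 1.21 CPM against 0, at least 661.6-fold higher (adjusted p = 0.0104). SEOa, which encodes a sieve element occlusion protein, rose by a log2 fold change of 9.70 ± 1.23 (adjusted p = 0.02). TMO6, a Dof transcription factor of vascular tissue, was at least 310.2-fold higher (adjusted p = 0.0411). AT5G57130, also called SMXL5, and AT4G29920, also called SMXL4, encode related proteins that promote phloem formation. The first rose by 11.49 ± 1.27 on the log2 scale (adjusted p = 0.0104), and the second was at least 579.4-fold higher (0.0289; at least 329.8-fold without BRXL2 1).

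Among the other genes higher in BRXL2 than in the libraries labelled BRX, the transcription factor AIL6 was at least 883.5-fold higher (adjusted p = 0.0104), and NAC028 at least 331.9-fold (0.0302). NAC096 had a ratio of 799.5 (counting interval 221.3 to 6602; adjusted p = 0.0344). The beta-glucosidase gene BGLU33 was at least 7530-fold higher (0.0289) but differed between its libraries, at 718 ± 907 CPM. ENODL9, an early nodulin-like gene, was at least 491.9-fold higher (0.0344) and MEE47 at least 490.3-fold (0.0302); both stood higher in BRXL2 1 (83.7 and 78.9 CPM) than in BRXL2 2 (10.1 and 14.6 CPM). Of 17 genes that passed, 16 were higher and 1 was lower, and 8 had no symbol. Those not yet named were AT1G26730, AT1G68330, AT1G70470, AT1G73850 and AT2G36570, each at least 325.7-fold higher. Without BRXL2 1 the bounds were 804.4 for BGLU33, 105.8 for ENODL9, 153 for MEE47 and for AT1G26730, 252.3 for AT1G68330, 119.6 for AT1G70470 and 242.5 for AT1G73850; without BRXL2 2 that of AT2G36570 was 268.2. The lower gene was AT3G20395, with a log2 fold change of -7.47 ± 1.13 (adjusted p = 0.0344). Other genes of low p in that direction did not pass: PRA1.B1 had a log2 fold change of -5.55 ± 0.98 (adjusted p = 0.079), AT4G20040 of -8.48 ± 1.58 (0.107) and AT2G30160 of -6.30 ± 1.25 (0.151); without BRX 1, AT4G20040 was at -4.79 and AT2G30160 at -3.94. AT4G03420 was at least 160.8-fold lower (0.211), carried by BRX 2 at 21.4 CPM against 1.74 in BRX 1, and at least 24.14-fold lower without BRX 2. At an unadjusted p under 0.05 there were 1609 genes, against 909 by chance.

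These calls rested on few libraries. Leaving out BRX 1, BRX 2, BRXL2 1, BRXL2 2, myrBRX 1 and myrBRX 2 in turn gave 6, 58, 35, 89, 147 and 221 genes, which held 4, 15, 11, 17, 17 and 17 of the 17. Without BRX 1 the genes still called were APL, AIL6, AT5G57130 and AT3G20395, and the adjusted p of the other 13 was 0.0509 to 0.0755 (SEOa 0.0509, TMO6 0.0639, BGLU33 0.0593). Without BRX 2, AT1G68330 (0.0511) and NAC096 (0.0524) did not pass. Without BRXL2 1, ENODL9 (0.175), MEE47 (0.1), AT1G26730 (0.11), AT1G68330 (0.0571), AT1G70470 (0.153) and NAC096 (0.0819) did not. DESeq2 called 759 genes, limma-voom called 0 with 1310 at an unadjusted p under 0.05, and edgeR on the compared libraries alone called 0 with 1106. EdgeR called 403 without a filter, 33 with the replicate number as a block and 10 with a stricter filter.

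Of the 14 phloem and vascular markers listed, 10 were tested. SWEET11, SWEET12, TMO5 and NAC045 did not pass the filter. They held 1 and 1, 2 and 2, 14 and 0, and 123 and 0 counts in the BRXL2 libraries. Members near 0 in the other lines could pass the filter only through the BRXL2 libraries, and so could only come out higher there. Of the 10 tested, 9 were higher in BRXL2 than in the libraries labelled BRX. The median log2 fold change was 6.91, or 5.74 with genes at 0 set to their bound. The list rose (camera adjusted p = 5.72e-12; adjusted p = 0.214 with an estimated correlation). APL passed over all genes, and 7 members were higher when adjusted over the list alone. SEOR1, a sieve element protein, had a log2 fold change of 6.24 ± 1.19 (adjusted p = 0.12), the receptor kinase gene BAM3 9.32 ± 1.90 (0.165) and the proton pump gene AHA3 6.48 ± 1.37 (0.197). SUC2, the sucrose transporter of companion cells, was the exception, at -1.57 ± 1.35. The mean log2 CPM of the list was 4.05 and 3.62 in the BRXL2 libraries and between -1.64 and -0.64 in the other 4.

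Guard cell markers had a fitted log2 fold change above 0 in BRXL2 against the libraries labelled BRX in 13 of 13 members (median 2.50, bounded 1.57). In 3 of these at least 1 group held 0 counts, and only 7 had both BRXL2 libraries above both labelled BRX. The list rose (camera adjusted p = 0.0018, and 0.768 with an estimated correlation). None passed singly over all genes or adjusted over the list alone, by edgeR. The myrosinase gene TGG2 had a log2 fold change of 3.08 ± 0.94 (adjusted p = 0.426) and the kinase gene OST1 2.57 ± 0.90 (0.462). The channel gene KAT2 had a ratio of 95.78 (counting interval 32.77 to 464.5), which rested on BRXL2 1: KAT2 stood at 9.31 CPM there and 0.187 in BRXL2 2, and its log2 fold change of 6.51 was 1.86 without BRXL2 1 and 10.48 without BRX 2. The list did not pass without BRX 1 (adjusted p = 0.0625) or BRXL2 1 (0.089). Genes of the G2/M phase fell in BRXL2 (16 of 19 lower, median -1.18, camera adjusted p = 0.00163; adjusted p = 0.807 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. The cyclin gene CYCB2;4 had a log2 fold change of -2.10 ± 0.90 (adjusted p = 0.547), which was -1.18 without BRX 1. AUR2, a mitotic kinase gene, had -4.82 ± 1.33 (0.37), carried by BRX 1 at 1600 CPM against 67.7 in BRX 2; without BRX 1 it was at -1.20. This list did not pass without BRXL2 2 (adjusted p = 0.225). Heat shock genes rose beside these groups (6 of 6 higher, median 1.60, camera adjusted p = 0.0193; adjusted p = 0.807 with an estimated correlation). HSP17.4, a small chaperone gene, had 3.04 ± 1.13 (adjusted p = 0.486), and 0 members passed over all genes or adjusted over the list alone. The heat shock list did not pass without BRX 1 (adjusted p = 0.0873), BRX 2 (0.147) or BRXL2 2 (0.459). The organelle share of counts was lower in both BRXL2 libraries than in both labelled BRX.

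In the preset stomatal regulators, no gene passed between BRXL2 and the libraries labelled BRX. MUTE, which drives the step to the guard mother cell, stood at 12.3 ± 1.58 CPM against 0.381 ± 0.539 (log2 fold change 4.99 ± 1.83, adjusted p = 0.486); BRX 2 held 0 counts of it, and the fitted value was 11.83 without BRX 1. POLAR, a polarity gene, stood at 35.4 ± 6.68 against 415 ± 462 CPM (-3.55 ± 1.12, adjusted p = 0.426). SPCH, the gene that starts the lineage, had a log2 fold change of -0.16 ± 1.00, TMM 0.01 ± 0.79, BASL -1.35 ± 1.00 and FAMA 1.30 ± 0.87. Without BRX 1, POLAR was at -1.32, SPCH at 1.22, BASL at 0.66 and TMM at -0.33; without BRX 2, SPCH was at -0.85, BASL at -2.16 and TMM at 0.46. Without BRXL2 1, FAMA was at 0.03, SPCH at -1.82 and TMM at 0.26; without BRXL2 2, FAMA was at 1.96, SPCH at 0.59 and TMM at -0.29. As a list, the 26 stomatal lineage regulators did not pass (adjusted p = 0.786).

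The comparison of myrBRX with BRXL2 used the libraries labelled BRX only in the filter, the scaling and the estimate of spread, but it rests on the myrBRX label and carries the same doubt. The phloem genes were low in myrBRX. APL fell to a ratio of 0.000445 (counting interval 5.39e-05 to 0.00161; adjusted p = 0.0292). SEOa and SEOR1, neighbouring genes of sieve element proteins, fell, with log2 fold changes of -9.41 ± 1.21 and -9.50 ± 1.39 (adjusted p = 0.0315 and 0.0472). AT5G57130 (SMXL5) fell, at -9.62 ± 1.17 (0.0292), as did AIL6, at -8.86 ± 1.13 (0.0363). TGG2, a myrosinase gene of the guard cell list, fell at -9.33 ± 1.29 (0.0365), from 37.6 ± 14.2 to 0.0541 ± 0.034 CPM.

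In all 9 genes passed between myrBRX and BRXL2, each lower in myrBRX. The others, each at adjusted p = 0.0472, were NAC096, AT4G29920 (SMXL4) and AT1G73850. Their ratios were 0.0011 (counting interval 0.000134 to 0.00399), 0.000471 (5.71e-05 to 0.0017) and 0.000365 (9.25e-06 to 0.00203). AT4G29920 was at 0.000943 without myrBRX 1, 0.000828 without BRXL2 1 and 0.000329 without BRXL2 2. AT1G73850 was at 0.00073 without myrBRX 2, 0.00065 without BRXL2 1 and 0.000254 without BRXL2 2. Higher genes of lowest p did not pass: the glutathione transferase gene GSTU24 had a log2 fold change of 6.50 ± 1.02 (adjusted p = 0.058), AT4G15610 7.29 ± 1.32 (0.101), AT4G23680 6.20 ± 1.18 (0.144), AT3G56200 7.76 ± 1.52 (0.162) and AT3G28850 6.08 ± 1.20 (0.162). At an unadjusted p under 0.05 there were 2255 genes, against 909 by chance. Leaving out BRX 1, BRX 2, BRXL2 1, BRXL2 2, myrBRX 1 and myrBRX 2 in turn gave 109, 69, 29, 119, 81 and 24 genes, which held 9, 9, 6, 9, 8 and 8 of the 9. NAC096 did not pass without BRXL2 1 (adjusted p = 0.0772), myrBRX 1 (0.0606) or myrBRX 2 (0.101), and AT1G73850 (0.0745) and AT4G29920 (0.0572) did not without BRXL2 1. DESeq2 called 1177 genes and limma-voom 0, with 2285 at an unadjusted p under 0.05. EdgeR called 657 without a filter, 42 with the replicate number as a block, 26 with its newer fit and 22 on the compared libraries alone. It called 5 each with a stricter filter, RLE factors and upper-quartile factors. Of the 9 genes, 7 were among the 16 that were higher in BRXL2 than in the libraries labelled BRX. Both comparisons use the BRXL2 libraries, which alone can give shared genes. In 20 simulations without true differences, the 16 and 9 genes of lowest p in these directions shared at most 2. This check was chosen after the overlap was seen. Each gene was drawn on its own there, so genes that vary together within a library were not covered. The check therefore does not decide whether the shared libraries alone gave the overlap.

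Phloem and vascular markers fell in myrBRX against BRXL2 (8 of 10 lower, median -7.39, bounded -5.72, camera adjusted p = 1.17e-09; adjusted p = 0.214 with an estimated correlation). APL and SEOR1 passed over all genes, and 6 members were lower when adjusted over the list alone. AHA3 had a log2 fold change of -7.11 ± 1.41 (adjusted p = 0.162) and BAM3 -7.67 ± 1.75 (0.201); myrBRX 2 held 0 counts of BAM3, whose fitted value was -13.91 without myrBRX 1. G2/M genes fell in 19 of 19 members (median -2.81, camera adjusted p = 8.94e-12; adjusted p = 0.751 with an estimated correlation); none passed over all genes by edgeR, and 13 were lower when adjusted over the list alone. The cyclin genes CYCB1;2, CYCB2;1 and CYCA1;1 had log2 fold changes of -5.47 ± 1.17 (adjusted p = 0.176), -4.85 ± 1.19 (0.21) and -3.74 ± 0.95 (0.21), with CYCB1;2 at -3.15 without BRXL2 1 and CYCB2;1 at -7.58 without myrBRX 1. The organelle share was lower in both myrBRX libraries than in both BRXL2 libraries, and heat shock genes did not pass (5 of 6 higher, median 0.85, adjusted p = 0.47).

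Stomatal lineage regulators fell in myrBRX against BRXL2 (22 of 26 lower, median -1.13, camera adjusted p = 0.0018; adjusted p = 0.807 with an estimated correlation). None passed over all genes, and 3 were lower when adjusted over the list alone. SDD1, a protease that limits stomatal density, had a log2 fold change of -3.60 ± 0.88 (adjusted p = 0.21), and FLP and MYB88, which end the guard mother cell division, had -2.97 ± 0.80 (0.221) and -3.25 ± 1.20 (0.309). MUTE stood at 0.0712 ± 0.027 against 12.3 ± 1.58 CPM (-7.37 ± 2.07, adjusted p = 0.225). SPCH had -1.39 ± 1.01, FAMA -1.09 ± 0.86, TMM -1.16 ± 0.80, BASL -0.18 ± 0.98 and POLAR 1.59 ± 1.04. Without BRXL2 1, SPCH was at 0.28, FAMA at 0.19 and BASL at 0.45, and without BRXL2 2, SPCH was at -2.13, FAMA at -1.75 and BASL at -0.61. Without myrBRX 1, SPCH was at -2.20, POLAR at 0.51 and BASL at 0.14, and without myrBRX 2, SPCH was at -0.87 and BASL at -0.59. Auxin transport genes fell (7 of 8 lower, median -2.12, camera adjusted p = 0.0278; adjusted p = 0.751 with an estimated correlation), 2 of them adjusted over the list alone and 0 over all genes. The influx carrier genes AUX1 and LAX2 had -3.05 ± 0.93 (adjusted p = 0.248) and -6.30 ± 2.05 (0.27), and the efflux carrier gene PIN4 -2.53 ± 1.14 (0.394). AUX1 was at -1.62 without BRXL2 1, and PIN4 at -4.03 without myrBRX 1. This list did not pass without BRXL2 1 (adjusted p = 0.0903), BRXL2 2 (0.111) or myrBRX 2 (0.118). Guard cell markers did not pass as a list (adjusted p = 0.996), and TGG2 was the member that passed.

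The comparison of myrBRX with the libraries labelled BRX asked what differs in cells of a line whose BRX construct is, by its name, myristoylated. Cell division genes were low in myrBRX. Of 19 G2/M genes, 18 were lower, with a median log2 fold change of -3.77, and the list fell (camera adjusted p = 1.61e-18; adjusted p = 0.585 with an estimated correlation). None passed over all genes by edgeR, and 17 were lower when adjusted over the list alone. The cyclin genes CYCA1;1 and CYCB2;4 had log2 fold changes of -5.62 ± 1.04 (adjusted p = 0.2) and -5.52 ± 1.05 (0.202). CDKB2;1, a kinase gene of mitosis, had -4.29 ± 0.91 (0.202), from 226 ± 18 CPM in the libraries labelled BRX to 11.5 ± 1.14 in myrBRX. CDC20.1, an activator of the anaphase-promoting complex, had -4.14 ± 0.87 (0.202). Genes of S phase and replication did not pass (11 of 13 lower, median -0.75, adjusted p = 0.893).

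Stomatal lineage regulators fell in myrBRX against the libraries labelled BRX (20 of 26 lower, median -1.45, camera adjusted p = 0.000652; adjusted p = 0.807 with an estimated correlation), 3 of them adjusted over the list alone and 0 over all genes. FLP had a log2 fold change of -3.65 ± 0.83 (adjusted p = 0.202), SOL1 -3.27 ± 0.89 (0.205) and SCRM2, a partner of SPCH, -3.94 ± 1.08 (0.207). SPCH had -1.55 ± 1.02, MUTE -2.38 ± 1.73, FAMA 0.21 ± 0.85, TMM -1.15 ± 0.80, BASL -1.53 ± 1.00 and POLAR -1.96 ± 1.05. Without BRX 1, SCRM2 was at -1.61, SPCH at -0.16, BASL at 0.49 and POLAR at 0.27, and MUTE was at a fitted 4.47 against a library with 0 counts. Without BRX 2, BASL was at -2.34 and TMM at -0.70. Without myrBRX 1, SPCH was at -2.36, POLAR at -3.04 and FAMA at 0.03, and without myrBRX 2, FAMA was at 0.38. Guard cell markers rose (10 of 13 higher, median 2.31, bounded 1.85, camera adjusted p = 0.0311; adjusted p = 0.807 with an estimated correlation), with 1 higher and 1 lower adjusted over the list alone. OST1 had 4.11 ± 0.96 (adjusted p = 0.202) and TGG1 2.70 ± 1.02 (0.29), while TGG2 had -6.25 ± 1.15 (0.2). The guard cell regulator SCAP1 was at least 19.45-fold higher (at least 11.04-fold without myrBRX 2). The list did not pass without BRX 1 (adjusted p = 0.129), BRX 2 (0.0822) or myrBRX 1 (0.0798).

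Heat shock genes rose in myrBRX beside the fall of the G2/M and stomatal lists (6 of 6 higher, median 2.69, camera adjusted p = 0.00368; adjusted p = 0.807 with an estimated correlation), 2 of them adjusted over the list alone and 0 over all genes. HSP17.4 had a log2 fold change of 4.06 ± 1.18 (adjusted p = 0.219) and HSP18.2 3.26 ± 1.13 (0.266), with HSP17.4 at 2.36 without myrBRX 1 and HSP18.2 at 5.11 without BRX 1. The list did not pass without BRX 2 (adjusted p = 0.0619) or myrBRX 1 (0.13). The organelle share moved the same way as the G2/M list, and was lower in both myrBRX libraries than in both labelled BRX.

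No single gene passed between myrBRX and the libraries labelled BRX by edgeR, where 2578 had an unadjusted p under 0.05, 1287 higher and 1291 lower, against 909 by chance. Other settings of edgeR did call genes: 724 without a filter, 29 with the replicate number as a block and 2 with its newer fit. DESeq2 called 1465, and limma-voom 0 with 2561 at an unadjusted p under 0.05. The lower genes of lowest p were AT3G20395 (log2 fold change -9.72 ± 1.25, adjusted p = 0.093), CDC20.2, a relative of CDC20.1 (-6.03 ± 0.95, 0.129), AT1G63100 (-5.48 ± 0.89, 0.129), the replication licensing gene CDT1B (-5.33 ± 0.94, 0.184) and AT1G26650 (-7.18 ± 1.32, 0.2; -4.66 without BRX 1). The higher ones were AT4G15610 with a ratio of 1854 (counting interval 634.5 to 8992; adjusted p = 0.104), JRG21, a jasmonate-regulated gene, with 1154 (319.6 to 9532; 0.104), the beta-amylase gene CT-BMY (6.90 ± 1.08, 0.129), AT3G17070 at least 181.9-fold (0.129), and AtCDC48B (5.33 ± 0.91, 0.161). None of these passed. AT4G15610 had a ratio of 744.5 without myrBRX 2, 2964 without myrBRX 1 and 927.2 without BRX 1. JRG21 had 577.2 without BRX 1. Without BRX 2, which held all their counts in that group, the 2 were at least 1005-fold and 416.9-fold higher. Leaving out BRX 1, BRX 2, BRXL2 1, BRXL2 2, myrBRX 1 and myrBRX 2 in turn gave 1, 327, 27, 67, 48 and 22 genes.

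The test of any difference among the lines called 41 genes. Each gene was assigned to the line whose mean log2 CPM lay farthest from the middle of the 3 means. This was BRXL2 on the high side in 29 genes, and myrBRX on the high side in 5 and the low side in 3. It was the libraries labelled BRX on the high side in 2 and the low side in 2. GSTU24 (adjusted p = 0.0159) was highest in myrBRX, and AT1G63100 (0.0498), CDC20.2 (0.0376) and TGG2 (0.0173) were lowest there. Leaving out BRX 1, BRX 2, BRXL2 1, BRXL2 2, myrBRX 1 and myrBRX 2 in turn gave 130, 661, 193, 391, 429 and 333 genes. The count was 1423 without a filter, 266 with the replicate number as a block and 173 with the newer fit.

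**Figure D2:**
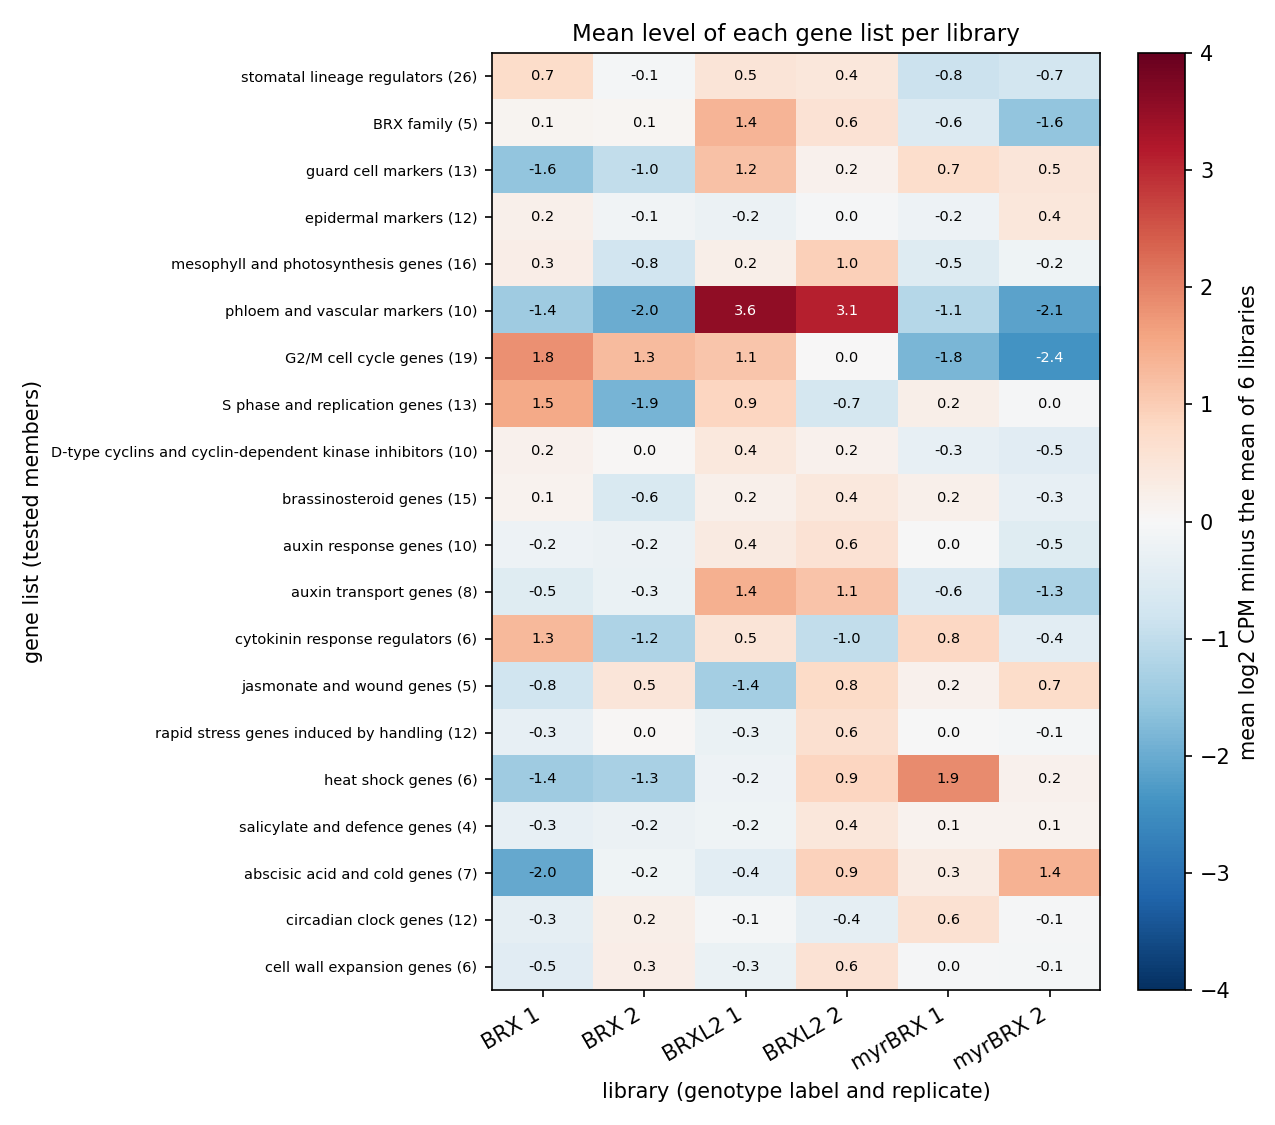
Mean log2 CPM of each gene list in each library, minus the mean of the 6 libraries (colour scale), with lists as rows of the map, tested members in brackets, and libraries along the horizontal axis. Phloem and vascular markers stood 3.55 and 3.12 above the mean in the BRXL2 libraries, and G2/M genes at -1.84 and -2.38 in the myrBRX libraries.

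The remaining lists did not pass camera in any comparison. The lowest of their 3 adjusted p was 0.064 for the BRX family, which holds the construct genes themselves, 0.13 for mesophyll and photosynthesis genes and 0.13 for abscisic acid and cold genes. It was 0.366 for D-type cyclins and kinase inhibitors, 0.526 for auxin response genes, 0.529 for circadian clock genes and 0.58 for epidermal markers. It was 0.607 for jasmonate and wound genes, 0.738 for cytokinin response regulators, 0.786 for rapid stress genes, 0.845 for brassinosteroid genes, 0.845 for cell wall expansion genes, 0.893 for S phase genes and 0.996 for salicylate and defence genes. Phloem markers did not pass between myrBRX and the libraries labelled BRX (median 0.83, bounded 0, adjusted p = 0.996), nor did auxin transport genes in either comparison with the libraries labelled BRX (0.529 for myrBRX and 0.193 for BRXL2). Adjusted over the list alone, epidermal markers had 2 higher and 1 lower member and auxin transport genes 1 lower in myrBRX against the libraries labelled BRX. The BRX family had 1 higher and 1 lower there, 1 higher in BRXL2 against the libraries labelled BRX and 1 lower in myrBRX against BRXL2. Median, mean and camera did not share a sign for epidermal, brassinosteroid, auxin response, rapid stress and salicylate genes in myrBRX against the libraries labelled BRX. The same held for stomatal, D-type cyclin, brassinosteroid and cell wall genes in BRXL2 against the libraries labelled BRX, and for guard cell, cytokinin and salicylate genes in myrBRX against BRXL2.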

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

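The settings of the glutathione S-transferase test, the newer quasi-likelihood fit, the omission of AT1G79245 and the further scalings of the gene lists were chosen after seeing the data; the other alternatives were fixed before the data were examined. Of 2029 alternative values of single genes, 1685 kept their direction and side of the threshold, 241 kept the direction and came to pass, 89 kept it and no longer passed, and 14 reversed. Of 156 values of single gene lists, 118 stayed and 38 no longer passed. With a correlation estimated per list, 0 lists passed in each comparison. For phloem markers the estimate was -0.015 in BRXL2 against BRX and 0.007 in myrBRX against BRXL2. It was -0.033 for auxin transport genes in myrBRX against BRXL2. These are not above the preset 0.01, so a stronger correlation does not account for the loss of these lists. The cause of that loss was not tested. For the other called lists the estimate lay above the preset. For G2/M genes it was 0.307 in myrBRX against BRX, 0.274 in BRXL2 against BRX and 0.338 in myrBRX against BRXL2. For stomatal regulators in myrBRX it was 0.145 against BRX and 0.114 against BRXL2. Against BRX, guard cell markers had 0.091 in myrBRX and 0.096 in BRXL2, and heat shock genes 0.704 and 0.649. The camera p of these lists at the preset leaves out that shared variation. The directional test of fry passed 0 lists in each comparison. Its test of change in either direction passed guard cell (adjusted p = 0.00988) and G2/M genes (0.0435) in myrBRX against BRX, the BRX family (0.00438) and phloem markers (0.0191) in BRXL2 against BRX, and guard cell (0.00438), brassinosteroid (0.00457), phloem (0.00988) and BRX family genes (0.0279) in myrBRX against BRXL2. Robust fitting, the omission of organelle loci and the omission of AT1G79245 left each count of genes within 1.5 times its value. In the order myrBRX against BRX, BRXL2 against BRX and myrBRX against BRXL2, DESeq2 called 1465, 759 and 1177 genes. Its log2 fold changes were 2.57 for BRX and -2.87 for BRXL2 in the first. BRXL2 was at 3.55 in the second and -6.42 in the third. In simulation 150 of 278, 119 of 229 and 138 of 257 DESeq2 calls were false, or 52 to 54%. That share depends on how many genes the simulation changed, so it is not the false share of the real calls. Without a filter edgeR called 724, 403 and 657 genes, 1423 among the 3 genotypes, and BRXL2 was at -6.43 between myrBRX and BRXL2 and passed; in simulation, which held no loci that the filter removes, its false calls were 3.33 to 13.5%, against 3.53 to 9.88% with the filter. Limma-voom called 0 in BRXL2 against BRX and 0 in myrBRX against BRXL2 (1310 and 2285 at an unadjusted p under 0.05). The stricter filter called 10 and 5 in these, and the compared groups alone 0 and 22. RLE factors called 5 and upper-quartile factors 5 between myrBRX and BRXL2. The newer fit called 2 genes in the first comparison, 26 in the third and 173 among the 3 genotypes, with BRXL2 at -6.44 in the third. The cause was not tested for these changes. Over all genes, replicate numbers paired the libraries weakly at most. Replicate deviations correlated at 0.127, 0.058 and 0.121 between groups, and 3 of 6 libraries correlated best with one of their own number. Some lists did shift alike in each line. The mean log2 CPM of S phase genes in replicates 1 and 2 was 5.38 and 1.99 in BRX. It was 4.72 and 3.16 in BRXL2, and 4.1 and 3.81 in myrBRX. Other lists, such as guard cell and epidermal markers, did not shift alike. A batch shared by replicate number is therefore not excluded. With the number as a block, edgeR called 29, 33 and 42 genes, 266 among the 3 genotypes, and BRXL2 was at -6.49 in the third comparison and passed.

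Leaving out 1 library leaves a lone sample in its group, which is assumed to vary like the other groups. The counts of genes then ranged from 1 to 327 in myrBRX against BRX, 6 to 221 in BRXL2 against BRX, 24 to 119 in myrBRX against BRXL2, and 130 to 661 among the 3 genotypes; the cause was not tested. Passing lists ranged from 2 to 4, 2 to 4 and 3 to 4. The log2 fold change of BRX was 1.88 to 3.11, 1.22 to 2.16 and 0.24 to 1.42, and that of BRXL2 -3.28 to -2.48, 3.3 to 3.95 and -6.87 to -6.11. Reversed values, none past the threshold, were MUTE (-3.37 to 4.47), BASL (-2.34 to 0.49) and POLAR (-3.04 to 0.27) in the first comparison. In the second they were SPCH (-1.82 to 1.22, with 0.59 without BRXL2 2), TMM (-0.33 to 0.46, with -0.29 without BRXL2 2) and BASL (-2.16 to 0.66). In the third they were SPCH (-2.20 to 0.28), FAMA (-1.75 to 0.19) and BASL (-0.61 to 0.45, with 0.14 without myrBRX 1). TMM was at 0 under the stricter filter in the second comparison and BASL at 0.13 with the block in the third; the cause was not tested. Voom moved the median log2 fold change of all genes from -0.03, 0.03 and -0.15 to 0.17, 0.14 and -0.04. At this depth and spread, simulated 4-fold changes were seldom recovered (0 to 1 of 50).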

Other observations

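The tests of S phase genes, of heat shock against G2/M genes, of both exchanges of libraries and of glutathione S-transferase genes were chosen only after the result was seen; the tests of further phloem genes, xylem genes, and GC content and length were written before theirs.

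Genes of the tau and phi classes of glutathione S-transferases, enzymes of detoxification, were higher as a set in myrBRX than in both other groups, by the preset correlation. Against the libraries labelled BRX, 24 of 27 were higher (median log2 fold change 2.11, camera adjusted p = 1.21e-06), and against BRXL2 21 of 27 (median 2.25, 3.24e-06); adjusted p = 0.176 with an estimated correlation in both. With each library left out in turn, the median was 1.91 to 4.35 (adjusted p = 2.44e-06 to 0.000261) and 1.2 to 2.93 (0.000126 to 0.0136); the lowest, 1.2, was without myrBRX 2 and the highest, 4.35, without BRX 2. GSTU24 stood at 65 and 155 CPM in the myrBRX libraries and between 1.19 and 5.22 CPM in the other 4. GSTU19 stood at 3110 and 7070 CPM in myrBRX and between 140 and 2100 CPM in the others. Members differed between the libraries labelled BRX: GSTF7 stood at 0.183 and 15.4 CPM, GSTU5 at 386 and 2720 CPM, and GSTU18 at 98.6 and 767 CPM, the latter above both myrBRX libraries (565 and 475 CPM). No member passed over all genes by edgeR in a pairwise test. Between BRXL2 and the libraries labelled BRX the class did not pass (15 of 27 higher, median 0.25, adjusted p = 0.557), but it passed without BRX 2 (24 of 30 higher, median 2.38, 0.00804). Heat shock genes also rose in myrBRX against the libraries labelled BRX (median 2.69), and the organelle share of counts was lowest in the myrBRX libraries, at 0.949 ± 0.552%.

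Phloem genes were high in the BRXL2 libraries, where a second list of sieve element and companion cell genes, none in the first lists, had 6 of 9 tested members above all other libraries, among them HCA2 at 69.5 and 41.3 CPM and CLE25 at 14.4 and 17.1 CPM; 2 of the 6 barely met this, CLE45 at 0.402 against 0.364 CPM and NAC020 at 1.1 against 0.854 CPM, while by chance 6.67% would be so placed and 8.56% of all tested genes were. By level, 4 of the 12 listed genes of the second phloem list were above 3 CPM in both BRXL2 libraries. Of 12 xylem genes, 1 was, LAC4, while IRX10 stood at 2.3 and 25.4 CPM. A mark that most genes of the second phloem list missed does not decide. By placement, 1 of 9 tested xylem genes lay above all other libraries, and XCP2 was highest in BRX 1, at 34.2 CPM. The xylem list as a set thus did not rise with the phloem genes. Several xylem genes were near 0 in all libraries, so vascular tissue as a whole is not excluded. Removing a trend on GC content and length left the median of the first phloem list at 6.87 (SE 1.86), which argues against that bias. Cells of the phloem lineage among those sorted from the BRXL2 line are a candidate explanation; companion cell genes went apart, with AHA3 at 88.6 and 95.6 CPM, but SUC2 at a log2 fold change of -1.57 ± 1.35 against the libraries labelled BRX, PP2-A1 at 1.51 and 0 CPM and SULTR2;1 at 0.276 and 0 CPM, so which cells of that lineage is open. Whether such cells were sorted or phloem genes were active in the stomatal lineage stays open, as does a difference between the lines, which was not tested apart from the sort; a gate on YFP would not remove cells in which the promoter is active.

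G2/M genes were low in the myrBRX libraries. After a trend on GC content and length was removed, the median log2 fold change against the libraries labelled BRX was -3.88 (SE 0.45), which argues against that bias as the cause. Fewer cells in all phases of the cycle cannot be told apart from a change in G2/M alone, because S phase genes varied within groups: the higher myrBRX library lay 2.11 log2 CPM above the lowest of the others. Heat shock during handling, which could lower cell cycle transcripts, cannot be excluded either, since the library with more heat shock transcripts had fewer G2/M transcripts in 2 of 3 groups, too few to decide. A difference in the state of the sorted cells or an effect of the construct remains open.

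BRX was lowest in the libraries labelled BRX. An exchange with a BRXL2 library is not favoured, since BRXL2 in the higher library labelled BRX was 10.9% of that in the lower BRXL2 library. An exchange of 1 library labelled BRX with 1 labelled myrBRX was not decided by the correlations. The myrBRX libraries correlated better with each other than with any labelled BRX by 0.08, within the range of replicate correlations (0.737 to 0.88). That test replaced one that the counts could not decide, and its margin was set after the correlations were seen. BRX 2 correlated at 0.737 with BRX 1 but at 0.753 to 0.8 with every library of both other lines. That was thus not particular to myrBRX. The G2/M genes were compared after their values were seen. Of 19, 18 were lower in both myrBRX libraries than in both labelled BRX, against 1 of 13 S phase genes. BRXL2 stood at 21.5 and 12.6 CPM against 150 and 95.5. Such an exchange would put both lines under each label, while these values separated by label. But the G2/M list had the lowest p of all lists in myrBRX against BRX, and its genes vary together (estimated correlation 0.307). Its separation was thus the reason for its choice, and BRXL2 is 1 gene, so such an exchange stays open. A wrong label on BRX 2 alone would leave BRX 1 with the lowest BRX level, at 6.1 CPM against 22.7 to 72.7 in the BRXL2 and myrBRX libraries. Also open is an exchange of both labels, which would give the lowest BRX level to the line named myrBRX. The changes given here for myrBRX would then be those of the BRX line. Low expression of the construct in the line with the lowest BRX level is open too. So is a difference in the kind of cells sorted from each line, which the labels do not settle. Reads of the YFP tag were not analysed here.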
